A study of Mus musculus with 11 samples.

How the data were processed

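Total RNA from L4 and L5 dorsal root ganglia of C57/BL6 mice was extracted with Trizol, converted to biotin-labelled cRNA with an Ambion MessageAmp kit and measured on Illumina bead arrays, 1 colour, per the labels. The labels place 11 arrays in 4 groups: young naive (3 arrays), young pre-conditioned (3), old naive (2) and old pre-conditioned (3). They do not state whether the arrays of a group come from separate animals or whether ganglia were pooled, so the p-values measure only the spread between these samples, which may be technical.

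The values analysed are the non-normalized probe intensities deposited by the authors, on a linear scale, for 25697 probes. The scanner software, its settings and any background subtraction are not given in the sources used here, and no value was below 107. No detection p-values accompany these intensities. The same table has 1 column, headed OldNV#3, that matches no labelled sample and was not used, so old naive ganglia are represented by 2 arrays. Processed intensities of the same arrays, deposited by the authors, form another table. RMA is named in the submitters' processing notes, with no version. Those values are on a linear scale, uncentred and of a single channel, so no ratio direction is involved. They keep the ranks of the unprocessed intensities (Spearman 1 on every array), have a median of 211 on each of the 11 arrays and lie within 1.50% of a quantile normalization on the log scale. They were used as an alternative and correlated with the main values at 0.994 on the log2 scale.

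Background was corrected with normexp (offset 50), as no detection p-values were at hand, followed by quantile normalization between arrays and log2, in limma 3.58.1 under R 4.3.3. Probes above the 40th percentile of their array on at least 2 arrays were kept, 17086 in all. The platform annotation gave 1 symbol for 23978 probes and several for 0, and 1719 probes were unnamed there. Symbols were updated through a RefSeq gene table of mouse assembly GRCm38.p6 by Entrez identifier (23962 probes) or accession (9), with 7 keeping the annotation's symbol, and 8 symbols changed. For each gene the probe with the highest mean over the 11 arrays stood for it, which left 11529 genes. Other probes of named genes were checked, 134 in all. Where the main probe was called, 0 were called in the opposite direction. That count leaves out main probes that were not called, such as that of Mbp after injury in young (0.03, against -1.05 on another probe). A further 32 probes were not called where the gene was, 7 of them for genes whose main probe also missed the threshold when all probes were tested. The number of arrays limits the precision. No arrays were identical, and the highest correlation between any pair was 0.996.

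One limma model with the 4 groups as cell means (lmFit and eBayes, 7 residual and 5.18 prior degrees of freedom) gave 6 contrasts: injury in young, injury in old, age in naive, age in injured, age averaged over both states, and the interaction. Tests were two-sided with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Counts adjusted over the list alone used the same model. Gene lists, 31 in number, covered neurons, glia, immune cells, vessels, matrix, possible neighbouring tissues and cellular processes. They were tested with camera (preset correlation 0.01), with camera at an estimated correlation and with fry, adjusted over the lists within each contrast. For a list score, the members' log2 levels relative to the young naive mean were averaged on each array.

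Groups, contrasts, tests, gene lists, the alternatives and the rule for named genes were fixed before the data were examined, except 2 alternatives and the tests named as later choices in the closing parts. Named per contrast were the 10 genes with the largest increase and the 10 with the largest decrease among those past the threshold whose arrays did not overlap between the groups compared. For the average over injury state this meant no overlap within either state, and for the interaction there was no such condition. Atf3, Sprr1a, Gap43, Jun, Gal, Npy and Mbp were to be reported whatever their values, with the sex chromosome genes as a sample check, and 1 further gene of this rule is not reported here. From each list described, up to 4 members with the smallest p past the threshold were eligible, or the 1 with the smallest p where none passed. Where fewer than 10 genes passed a contrast, all of them and the 5 with the smallest p were taken.

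Alternatives changed one choice at a time: no background correction, cyclic loess, median scaling, the processed values of the authors, no filter or a stricter one (above the 60th percentile on all 11 arrays), all probes, averaged probes, a replicate block, a trended and robust variance model, array weights, only the groups compared, a minimum 2-fold change and leaving out each array in turn. The procedure was tested on simulated data that took each gene's mean and moderated SD from these arrays, with 1 simulated set per contrast. Normal noise was drawn independently for each gene and array, with the same SD in all groups. Outlying arrays and correlated genes were not represented, so recovery and false calls may differ in the real data. Each simulated set held many changed genes, which eases the adjusted threshold, so recovery can be lower where few genes differ. Of genes changed by 0.5, 1 and 2 on the log2 scale, the injury contrasts recovered 55.2%, 100% and 100% in young and 37.3%, 95.5% and 100% in old animals. The age contrasts recovered 31.3%, 98.5% and 100% in naive animals, 56.7%, 98.5% and 100% in injured animals and 89.6%, 100% and 100% averaged over injury state, and the interaction 2.99%, 88.1% and 100%. False calls were 16 of 186 and 3 of 158 calls for injury in young and old, 12 of 165, 7 of 177 and 11 of 204 for age in naive, injured and averaged, and 9 of 136 for the interaction, so in 4 of the 6 contrasts above the 5% aimed at. All statistics were computed in R, and probe annotation and plots were made in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.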

Results

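Expression was measured in the L4 and L5 dorsal root ganglia of mice, the clusters of sensory neurons and their satellite and Schwann cells whose axons run in the sciatic nerve. Young animals were 2 months old and old animals 24 months old. The labels call the samples naive or pre-conditioned. The series design, whose wording of days is hard to read, was taken to mean day 0 for naive animals and 5 days after sciatic nerve crush for pre-conditioned animals. The young groups held 3 naive and 3 pre-conditioned arrays, the old groups 2 naive and 3 pre-conditioned arrays. The median probe intensity before normalization ran from 171 on old naive 2 to 296 on young pre-conditioned 3, and old pre-conditioned 1 was nearly as bright at 285. Of 11529 genes tested, changes are given as log2 differences with their standard error, and all tests were two-sided.

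The first principal component held 57.7% of the variance and separated every naive array from every pre-conditioned array. Old pre-conditioned 1 lay apart from the rest on the second component (14.2% of the variance), at -26.4, and had the lowest mean correlation with its own group, 0.984. The Y-linked genes Kdm5d, Uty and Eif2s3y were measured on every array, with no detection p-values to test whether their transcripts were present. Xist, which marks a second X chromosome, lay between 6.33 and 6.82 on the log2 scale. None of these sex chromosome genes passed the test in any comparison. Skeletal muscle transcripts stood out on 1 array: the mean of the 9 measured markers lay 1.68 above the young naive mean on young pre-conditioned 3, and between -0.20 and 0.07 on the other arrays.

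Crush injury in young animals was the comparison that asked how the ganglia of an injured nerve differ from intact ones. Npy, which encodes neuropeptide Y, rose by 5.66 ± 0.18 on the log2 scale (probe ILMN_2946520, n = 3 and 3, adjusted p = 9.46e-10), from a level of 7.26 ± 0.18 (SD) whose distance from background is unknown. Atf3, a transcription factor induced in axotomized neurons, rose by 5.05 ± 0.12 (probe ILMN_2619408, adjusted p = 5.62e-11), from 7.32 ± 0.13 (SD) to 12.37 ± 0.06. Other large increases were those of the cholecystokinin receptor gene Cckbr (5.43), the orphan receptor gene Gpr151 (5.33) and Sprr1a, a small proline-rich protein linked to axon outgrowth (4.51). They were followed by the peptidase gene Ecel1 (4.43), the serotonin transporter gene Slc6a4 (4.17) and Wfdc3 (4.16). Speer3 (4.56) and Speer1 (4.14) rose too, but belong to a family of near-identical genes whose transcripts the probes may share. Gal, encoding the neuropeptide galanin, rose by 3.26 ± 0.13, the transcription factor gene Jun by 1.40 ± 0.13 and Gap43, a growth cone protein gene, by 1.38 ± 0.29.

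In all, 997 genes rose and 1087 fell after injury in young ganglia by limma at an adjusted p under 0.05, 2084 together, of which 309 changed at least 2-fold. Increases made up 47.8% of these calls, but 38.7% under median scaling and 54.0% under cyclic loess, so the balance of increases and decreases is not settled. Among the nerve injury and regeneration genes, 34 of 39 measured members rose and 0 fell (35 rose when adjusted over the list alone). Their median change was 1.30, and camera, which compares a list with all other genes, gave an adjusted p of 2.26e-38 (adjusted p = 0.014 with an estimated correlation).

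**Figure D1:**
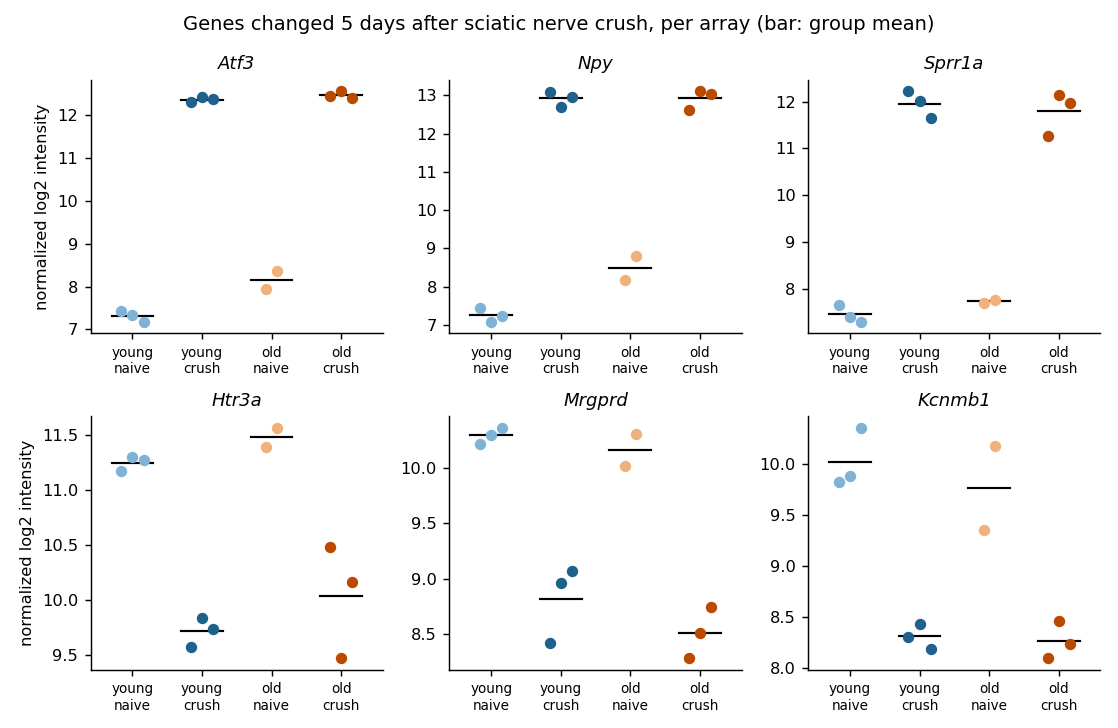
Log2 normalized intensity of 6 genes on each of the 11 arrays, grouped as young naive, young pre-conditioned, old naive and old pre-conditioned, with each point 1 array and each bar a group mean. Atf3, Npy and Sprr1a lie higher, and Htr3a, Mrgprd and Kcnmb1 lower, on every pre-conditioned array than on any naive array of the same age.

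Genes by which sensory neurons detect stimuli and fire fell in the injured young ganglia. Large decreases were those of Kcnmb1, a subunit of large-conductance potassium channels (-1.71 ± 0.20), the signalling regulator Rgs8 (-1.57), Htr3b (-1.55) and Htr3a (-1.53), subunits of a serotonin-gated channel. Vstm2b fell by 1.48, and receptor genes of small-diameter sensory neurons fell as well, among them Mrgprd (-1.47), Mrgpra3 (-1.45) and Mrgprb5 (-1.40). Of the 22 measured ion channels and receptors of sensory neurons, 18 fell and 0 rose, both over all genes and adjusted over the list alone, with a median of -0.70 (camera adjusted p = 2.59e-11, but adjusted p = 0.0572 with an estimated correlation). Among the 11 neuropeptides and trophic receptors, 6 fell and 1 rose on either adjustment, that is over all genes and adjusted over the list alone. The decreases included tyrosine hydroxylase, Th (-1.39), the calcium-binding protein gene Pvalb (-0.64), the neurotrophin receptor gene Ntrk3 (-0.62, but 0.06 and -0.28 on other probes, which were not called) and the substance P precursor gene Tac1 (-0.60). The list had a median of -0.60 (camera adjusted p = 0.00705, adjusted p = 0.135 with an estimated correlation), and of -0.39 without young pre-conditioned 3.

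Macrophage genes rose together: 19 of 21 measured markers were higher after injury, also when adjusted over the list alone, with a median of 1.30 (camera adjusted p = 6.79e-22, adjusted p = 0.0118 with an estimated correlation). The lysozyme gene Lyz2 rose by 1.85 ± 0.11, although another of its probes was not called, and the Fc receptor gene Fcgr3 by 1.56 ± 0.10. C1qa, C1qb and C1qc, which encode the chains of the first complement component and are counted among both macrophage and complement genes, rose by 1.55, 1.77 and 2.08. They and C4b (0.66) were the 4 of 8 complement genes that rose, with 4 adjusted over the list alone (median 0.45, camera adjusted p = 0.000105, adjusted p = 0.0572 with an estimated correlation). Of 20 chemokines and cytokines 9 rose (10 adjusted over the list alone), among them Ccl8 (2.25), Ccl12 (1.95), Ccl9 (1.61) and Tgfb1 (1.29). The list had a median of 0.31 (camera adjusted p = 3.54e-07, adjusted p = 0.0572 with an estimated correlation). Of 10 neutrophil markers 6 rose (7 adjusted over the list alone), including Retnlg (1.46), the antimicrobial peptide gene Camp (1.40) and S100a9 (1.34). Their median was 1.07 (camera adjusted p = 0.000228, adjusted p = 0.372 with an estimated correlation), and 0.71 without young pre-conditioned 3, whose mean score of 1.47 exceeded the 0.69 and 0.67 of young pre-conditioned 1 and 2. Of 7 MHC class II genes 2 rose (4 adjusted over the list alone, median 0.43, camera adjusted p = 0.00705, adjusted p = 0.41 with an estimated correlation). That list's call was lost without young naive 2, its median ranging from 0.32 to 0.69 over the fits that left out 1 array, highest without young naive 3.

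Genes of the matrix, of cell division and of fat were also among those that rose. The matrix gene Lum, encoding lumican, rose by 0.93 ± 0.12, and 4 of 14 collagens and fibroblast markers rose (7 adjusted over the list alone), with a median of 0.44 (camera adjusted p = 0.000228, adjusted p = 0.28 with an estimated correlation). Of 16 proliferation genes 4 rose, also when adjusted over the list alone, led by the spindle protein gene Prc1 at 2.38 ± 0.09, but their median was 0.20 (camera adjusted p = 0.00544, adjusted p = 0.0652 with an estimated correlation). Of only 3 measured adipocyte markers 2 rose on either adjustment, over all genes and adjusted over the list alone: Car3, a carbonic anhydrase gene abundant in fat and in skeletal muscle (3.86 ± 0.18), and Adipoq (0.73 ± 0.18). Their median was 0.73 (camera adjusted p = 0.00544, adjusted p = 0.169 with an estimated correlation). Adipoq lost its call without young naive 2, young pre-conditioned 1 or young pre-conditioned 3, ranging from 0.56 to 0.88 over those fits. Of 10 ageing and senescence genes 3 rose, also when adjusted over the list alone, with a median of 0.22 (camera adjusted p = 0.0331, adjusted p = 0.138 with an estimated correlation). That call was lost without young naive 2 or young pre-conditioned 1, with medians from 0.15 to 0.24 over the fits without 1 array.

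The remaining lists did not pass camera in young animals. Median changes were 0.13 for Schwann cell myelin genes, -0.07 for repair Schwann cell genes, 0.03 for satellite glia, -0.36 for glia of the central nervous system, -0.11 for the neuronal cytoskeleton and -0.14 for oxidative phosphorylation. They were 0.10 for cholesterol synthesis, 0.13 for lysosomal genes, 0.09 for immediate early and heat shock genes, 0.12 for the interferon response, 0.05 for MHC class I and 0.06 for T and NK cell markers. B and plasma cell markers had a median of -0.02, red blood cell markers 0.19, endothelial markers 0.01, pericyte and smooth muscle markers 0.09, skeletal muscle markers 0.62, bone and cartilage markers -0.02 and sex chromosome genes 0.02. Camera's adjusted p ran from 0.0788 to 0.987 over these lists. In each comparison the median, the mean and the test of a list that passed camera there had one sign. Lists that did not pass could differ in sign, as in this comparison MHC class I did with a mean of -0.02 and the pericyte list with a mean of -0.04. Mbp, the myelin basic protein gene, measured 0.03 ± 0.09 on its brightest probe, but another of its probes gave -1.05 (adjusted p = 0.000271) and a further one 0.11 (adjusted p = 0.926).

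Injury in old animals was measured in the same way. Gpr151 rose by 5.12 ± 0.12 (n = 2 and 3, adjusted p = 1.69e-10), Cckbr by 4.57, Npy by 4.43 ± 0.20 (adjusted p = 3.39e-08) and Atf3 by 4.32 ± 0.13 (adjusted p = 9.39e-10). Slc6a4 rose by 4.22, Wfdc3 by 4.18, Sprr1a by 4.06 and the lipase gene Lipn by 3.85, and Speer3 (4.39) and Speer1 (3.76) rose again. Gal rose by 3.27 ± 0.15, Jun by 1.18 ± 0.14 and Gap43 by 1.70 ± 0.32, which was no longer called without old naive 1 and ranged from 1.15 to 2.25 over the fits that left out 1 array. Among the decreases were those of the potassium channel partner Kcnip2 (-1.80, lost without old naive 2, -2.14 to -1.23 over the same fits), Ly6h (-1.69), Htr3b (-1.68) and Mrgprd (-1.65). Next came Vwc2l (-1.54), Kcnmb1 (-1.51), Igsf21 (-1.50) and Htr3a (-1.44). Mbp measured -0.04 on its brightest probe and did not pass, but other probes gave -0.86 (adjusted p = 0.0031) and -0.56 (adjusted p = 0.538). By limma 932 genes rose and 974 fell, 1906 in all, of which 300 changed at least 2-fold. Increases were 48.9% of the calls, 45.2% under median scaling and 55.9% under cyclic loess. That count rests on only 2 naive arrays: it was 982 without old naive 1, 1224 without old naive 2 and 911 when only the old arrays were fitted.

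By list, 33 of 39 regeneration genes rose (35 adjusted over the list alone), with a median of 1.32 (camera adjusted p = 3.27e-36, adjusted p = 0.0166 with an estimated correlation). Of the ion channels and receptors 17 of 22 fell (18 adjusted over the list alone, median -0.79, camera adjusted p = 2.5e-11, adjusted p = 0.0485 with an estimated correlation). Macrophage markers rose in 19 of 21 cases, also when adjusted over the list alone, with Fcgr3 at 1.56 and Laptm5 at 1.44. Their median was 1.44 (camera adjusted p = 5.82e-20, adjusted p = 0.0157 with an estimated correlation). Among chemokines and cytokines 10 of 20 rose (12 adjusted over the list alone, median 0.51, camera adjusted p = 2.7e-08, adjusted p = 0.0485 with an estimated correlation), with Ccl8 at 2.22 and Ccl9 at 2.01. Proliferation genes rose in 8 of 16 cases on either adjustment, over all genes and adjusted over the list alone, including Prc1 (2.36), the cell cycle kinase gene Cdk1 (0.95) and the replication helicase gene Mcm6 (0.92, but 0.45 and not called on another probe). Their median was 0.31 (camera adjusted p = 2.18e-05, adjusted p = 0.0199 with an estimated correlation). These calls of the regeneration, channel, macrophage, chemokine and proliferation lists in old animals, and of the regeneration and macrophage lists in young animals, were the camera calls that held with an estimated correlation in the whole data set.

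Granule and antiviral genes were among the other changes in injured old ganglia. Of 10 neutrophil markers 8 rose (9 adjusted over the list alone), with S100a9 at 2.31 ± 0.34, the granule protein gene Ngp at 2.24 ± 0.35 and Retnlg at 2.17. The median was 1.99 (camera adjusted p = 2.7e-08, adjusted p = 0.19 with an estimated correlation). Interferon response genes rose in 8 of 22 cases (9 adjusted over the list alone), among them Usp18 (1.40 ± 0.31, 0.79 and not called on another probe) and Rsad2 (0.76 ± 0.18). As a list they had a median of 0.40 (camera adjusted p = 8.67e-05, adjusted p = 0.23 with an estimated correlation). Usp18 and Rsad2 were not called without old naive 1, ranging from 1.26 to 1.55 and from 0.57 to 0.92 over the fits without 1 array. Complement rose in 4 of 8 genes (5 adjusted over the list alone, median 0.59, camera adjusted p = 0.000125, adjusted p = 0.0544 with an estimated correlation). Collagens and fibroblast markers had a median of 0.29 with 2 of 14 past the test on either adjustment, over all genes and adjusted over the list alone (camera adjusted p = 0.0122, adjusted p = 0.442 with an estimated correlation). MHC class II genes had 1 of 7 past the test (0 adjusted over the list alone) and a median of 0.50 (camera adjusted p = 0.0204, adjusted p = 0.472 with an estimated correlation). Neuropeptides and trophic receptors fell in 5 of 11 cases and rose in 1, the same adjusted over the list alone (median -0.33, camera adjusted p = 0.0438, adjusted p = 0.208 with an estimated correlation). Of 4 markers of central glia 2 fell on either adjustment, over all genes and adjusted over the list alone, including the water channel gene Aqp4 at -0.76 ± 0.11 (median -0.33, camera adjusted p = 0.0469, adjusted p = 0.19 with an estimated correlation). The calls of these smaller lists depended on single arrays. The collagen call was lost without old pre-conditioned 1 (0.19 to 0.37 over the fits without 1 array), and that of MHC class II without old naive 1 or old pre-conditioned 1 (0.35 to 0.59). The neuropeptide call was lost without old naive 1 or old pre-conditioned 2 (-0.43 to -0.30), and that of central glia without old naive 1, old naive 2, old pre-conditioned 1 or old pre-conditioned 3 (-0.40 to -0.31).

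**Figure D2:**
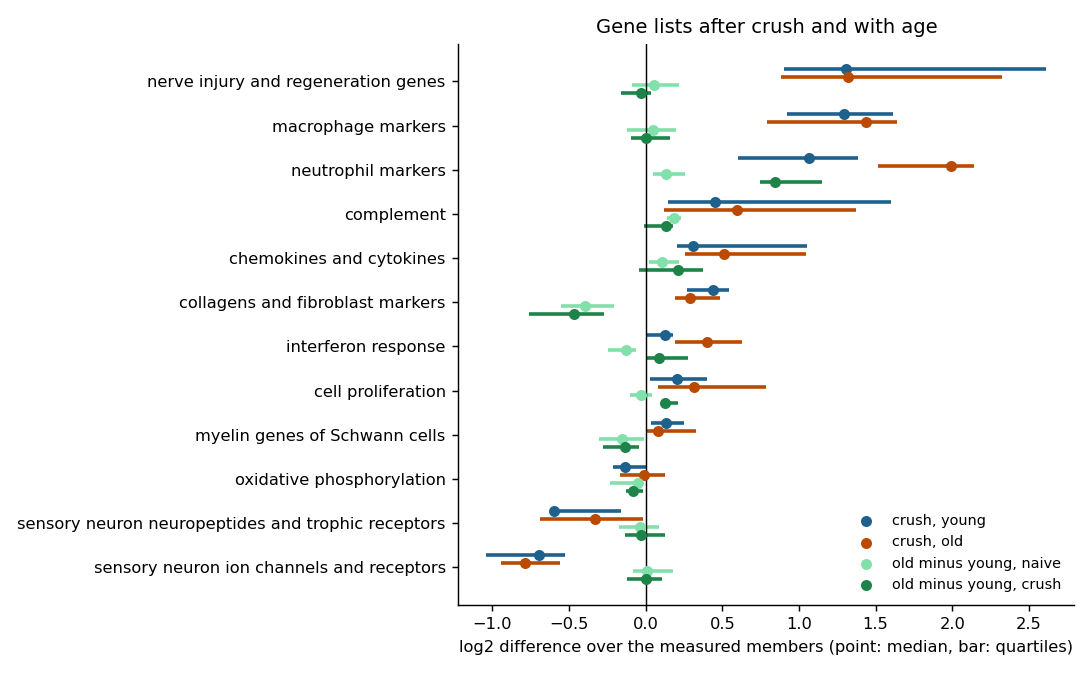
Median log2 change of 12 gene lists in 4 comparisons (injury in young, injury in old, age in naive and age in injured ganglia), with bars spanning the quartiles of the list's members. Regeneration genes (1.30 and 1.32) and macrophage markers (1.30 and 1.44) lie far above 0 in both injury comparisons, and collagens lie below 0 in both age comparisons.

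Injury responses at the 2 ages were then set against each other, gene by gene. Across all genes tested the old response correlated with the young one at r = 0.884 (jackknife SE 0.0491), with a total least squares slope of 1.03 (SE 0.137) of old on young. Genes are not independent replicates, so no p is given for this r. Leaving out single arrays gave r from 0.821 to 0.881 and slopes from 0.990 to 1.14. Total least squares takes both axes to be equally noisy, but the median standard error was 0.136 in old and 0.122 in young. Over the genes called at either age the slope was 0.995. Both ages shared 715 genes that rose, against 80.6 if the calls were independent, and 745 that fell, against 91.8, and 0 genes were called in opposite directions. The counts under independence are likely too low, since both tests share each gene's variance estimate. Of the 1460 genes called at both ages 672 (46.0%) changed less in old ganglia.

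No single gene passed the test for a response to injury that differed between the ages. The interaction test by limma called 0 genes, with 351 at an unadjusted p under 0.05 and a smallest adjusted p of 0.999, and 0 in every alternative run. The genes with the smallest p, none past the threshold, were Npy (-1.23 ± 0.27, so a smaller rise in old ganglia), the protease gene Sppl2c (1.01 ± 0.21), Gpnmb, a glycoprotein gene of macrophages (1.24 ± 0.28, 0.60 on a second probe), Auh (-0.67 ± 0.15) and the ephrin receptor gene Epha3 (-0.80 ± 0.18). Other probes gave -0.0025 for Sppl2c, and -0.09 and 0.12 for Epha3. Atf3 measured -0.73 ± 0.18, Gap43 0.32 ± 0.43, Jun -0.21 ± 0.19, Sprr1a -0.45 ± 0.31, Gal 0.00 ± 0.20 and Mbp -0.07 ± 0.13, each with an adjusted p of 0.999. For Npy and Atf3 the smaller rise in old ganglia went with a higher level in the old naive arrays. Their levels in injured ganglia did not differ between the ages past the threshold. Data were simulated with this design, with independent noise and no outlying array. There the interaction test recovered 88.1% of genes changed by 1 on the log2 scale and 2.99% of those changed by 0.5. The simulated set gave 136 calls, which ease the adjusted threshold for each gene, whereas the real test gave 0. These shares therefore do not show that a lone gene changed by 1 would be found.

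**Figure D3:**
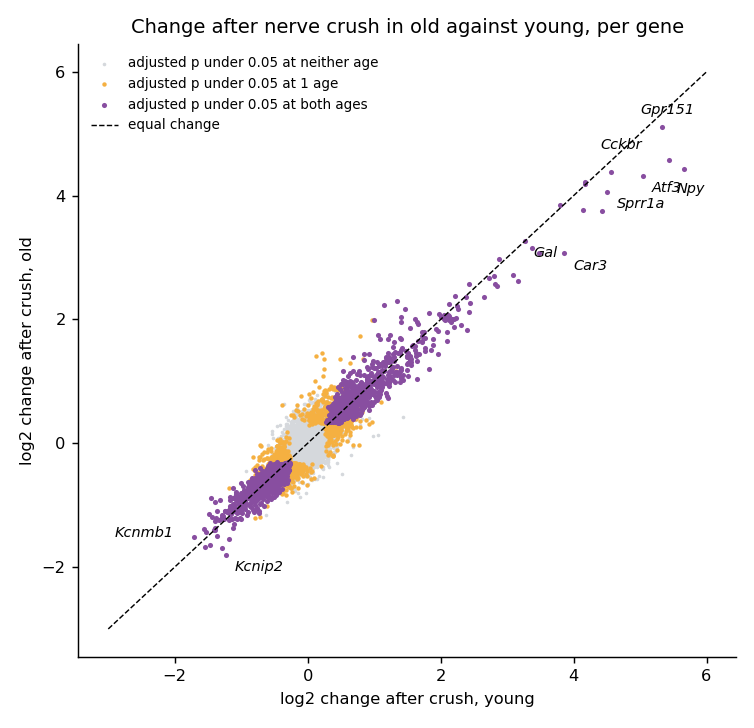
Log2 change after injury in old ganglia (vertical) against that in young ganglia (horizontal), 1 point per gene over the 11529 genes tested. Points lie along the diagonal (r = 0.884), with Npy, Atf3, Gpr151 and Cckbr at the upper right.

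Age without injury was compared between the 2 old naive and the 3 young naive arrays. Ccl8, a chemokine gene that attracts monocytes, was higher in old naive ganglia by 1.76 ± 0.16 on the log2 scale (adjusted p = 0.00139), and Csprs by 1.84 ± 0.18 (adjusted p = 0.00139). Higher too were the injury-induced genes Npy (1.23 ± 0.20, adjusted p = 0.0404) and Atf3 (0.83 ± 0.13, adjusted p = 0.037), Azgp1 (1.11, but 0.06 on a second probe), the ceramidase gene Acer2 (0.97), the protocadherin gene Pcdhb3 (0.85), Nxph1 (0.69) and Vmn1r181 (0.65). Sprr1a (0.28 ± 0.23), Gal (0.03 ± 0.15), Jun (0.20 ± 0.14), Gap43 (-0.46 ± 0.32) and Mbp (0.10 ± 0.10) did not pass. Lower in old naive ganglia were Tyrp1, a melanin synthesis gene (-1.48 ± 0.16), the adhesive glycoprotein gene Vtn (-1.08 ± 0.16), the homeobox gene Hoxb5 (-0.82), the collagen chaperone gene Serpinh1 (-0.77), the collagen gene Col26a1 (-0.65) and Nrep (-0.61). These 9 higher and 6 lower genes were all that limma called. Ccl8 and Csprs passed in each of the 11 fits without 1 array, and the other 13 each lost the call in at least 1, always including the fit without old naive 2. The count was 4, 7 and 5 without young naive 1, 2 and 3, and 8, 5 and 8 without young pre-conditioned 1, 2 and 3. It was 6 and 2 without old naive 1 and 2, and 23 and 7 without old pre-conditioned 1 and 3. Over those fits Npy ranged from 0.92 to 1.54 and Atf3 from 0.61 to 1.04.

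Collagens and fibroblast markers had the smallest camera p for age in naive ganglia, with a median of -0.39 and 11 of 14 members below 0. No member passed over all genes, 4 fell adjusted over the list alone, and camera gave an adjusted p of 5.02e-06 (adjusted p = 0.448 with an estimated correlation). The type IV collagen gene Col4a1 measured -0.42 ± 0.13 (adjusted p = 0.545). Chemokines and cytokines had a median of 0.10, with Ccl8 alone past the test on either adjustment, over all genes and adjusted over the list alone (camera adjusted p = 0.0178, adjusted p = 0.448 with an estimated correlation). Complement genes had a median of 0.18 (camera adjusted p = 0.0355, adjusted p = 0.448 with an estimated correlation), with 0 past the test, also when adjusted over the list alone. Myelin genes had a median of -0.16 (camera adjusted p = 0.00877, adjusted p = 0.448 with an estimated correlation). Interferon response genes had a median of -0.13 (camera adjusted p = 0.00904, adjusted p = 0.52 with an estimated correlation) and oxidative phosphorylation genes -0.05 (camera adjusted p = 0.013, adjusted p = 0.448 with an estimated correlation), with 0 members past the test in each on either adjustment. Apart from the collagens these calls depended on single arrays. The chemokine (0.05 to 0.15) and complement (0.15 to 0.20) calls were lost without young naive 2 or old naive 2, and the myelin call without old naive 2 (-0.20 to -0.06). The interferon call was lost without young naive 1 or old naive 1 (-0.25 to -0.08, lowest without old naive 2), and the oxidative phosphorylation call without old naive 1 (-0.07 to -0.03), all ranges being those of the median over the fits without 1 array. With brighter probes only, the chemokine median was -0.08, and under median scaling the oxidative phosphorylation median was 0.03.

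At 5 days after crush, old and young ganglia again differed in Ccl8, which was higher in old by 1.73 ± 0.15 (n = 3 and 3, adjusted p = 0.000308). Gpnmb was higher by 1.71 ± 0.18 (adjusted p = 0.00212), although a second probe gave 0.63 (adjusted p = 0.451). Csprs (1.21), Acer2 (1.09), Azgp1 (1.09, 0.01 on a second probe), Vmn1r181 (0.93), Mgarp (0.87) and Cd209b, a lectin gene of macrophages (0.81), were higher as well. So were a pair of neutrophil genes, Cd177 (0.98, 0.44 and adjusted p = 0.225 on a second probe) and the peptidoglycan recognition gene Pglyrp1 (0.97). Lower in injured old ganglia were Pmp2, a myelin lipid-binding protein gene (-1.45 ± 0.22), Lox, whose product crosslinks collagen (-1.41 ± 0.20), Col26a1 (-1.14 ± 0.09) and Vtn (-1.06 ± 0.14). Tyrp1 (-1.01), the smooth muscle actin gene Actg2 (-0.91), the matrix gene Spon2 (-0.84), the endothelin receptor gene Ednrb (-0.69, -1.35 and -0.73 on other probes, which were not called), Aoc3 (-0.69) and the circadian transcription factor gene Dbp (-0.67) were lower too. Atf3 (0.10 ± 0.12), Npy (0.00 ± 0.18), Sprr1a (-0.17 ± 0.21), Gal (0.03 ± 0.13), Jun (-0.02 ± 0.13), Gap43 (-0.14 ± 0.29) and Mbp (0.03 ± 0.09) did not differ past the threshold.

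In all 14 genes were higher and 13 lower in injured old than in injured young ganglia by limma. The count was 45 without old pre-conditioned 1, 10 without young pre-conditioned 1, 16 without old pre-conditioned 2, 12 without old pre-conditioned 3 and 12 when only the injured arrays were fitted. On their main probes Acer2, Azgp1, Ccl8, Cd209b, Col26a1, Gpnmb, Vmn1r181 and Vtn passed in each fit without 1 array. Csprs (1.11 to 1.27) and Mgarp (0.80 to 0.90) were lost without young pre-conditioned 1, and Lox (-1.58 to -1.28) without young pre-conditioned 1, old pre-conditioned 2 or old pre-conditioned 3. Pmp2 (-1.64 to -1.30) was lost without young pre-conditioned 1, young pre-conditioned 3 or old pre-conditioned 3, Pglyrp1 (0.84 to 1.11) without young pre-conditioned 1, young pre-conditioned 2 or old pre-conditioned 3. Spon2 (-0.91 to -0.73) was lost without young pre-conditioned 1 or old pre-conditioned 3, and Tyrp1 (-1.20 to -0.87) without young pre-conditioned 2, old pre-conditioned 2 or old pre-conditioned 3. Actg2, Aoc3, Cd177, Dbp and Ednrb were lost without young pre-conditioned 1, without old pre-conditioned 3 and without other arrays, passing in 2 to 4 of the 11 fits.

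**Figure D4:**
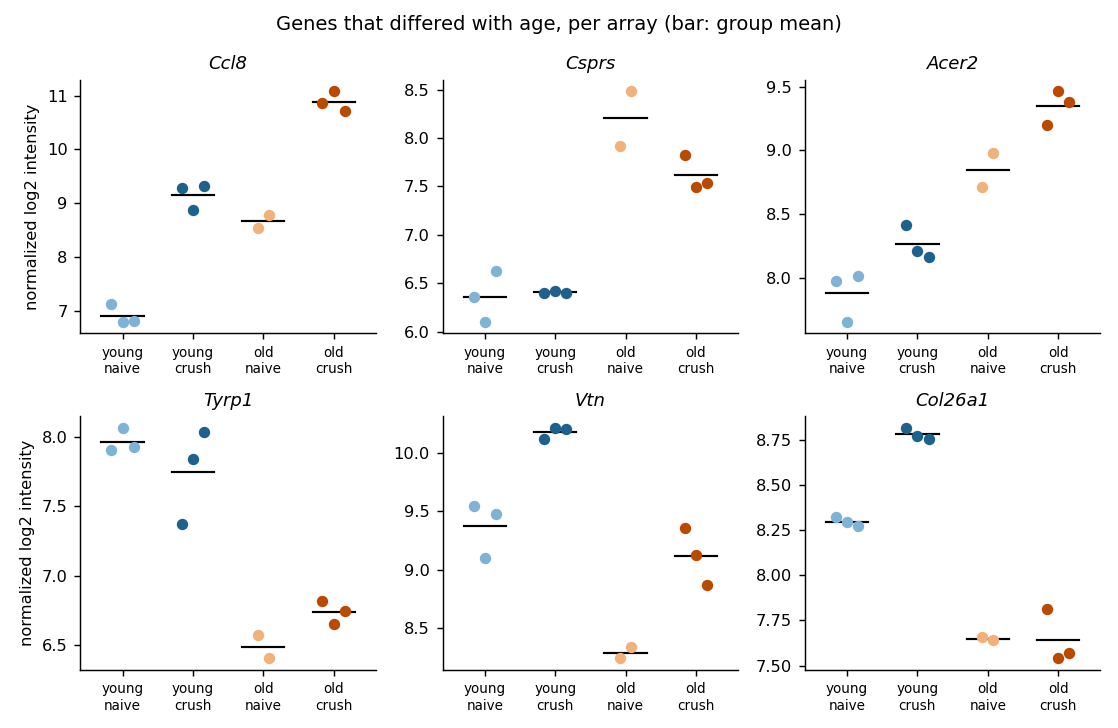
Log2 normalized intensity of Ccl8, Csprs, Acer2, Tyrp1, Vtn and Col26a1 on each of the 11 arrays, with each point 1 array and each bar the mean of its group. Ccl8, Csprs and Acer2 lie higher, and Tyrp1, Vtn and Col26a1 lower, in old than in young ganglia of the same injury state.

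Neutrophil markers were higher and collagens lower in injured old ganglia. All 10 measured neutrophil markers lay above 0, with a median of 0.84 and Lcn2, an iron-sequestering granule protein gene, at 1.57 ± 0.29 (adjusted p = 0.0693). None passed over all genes, 9 of 10 were higher adjusted over the list alone, and camera gave an adjusted p of 9.61e-14 (adjusted p = 0.175 with an estimated correlation). All 14 collagens and fibroblast markers lay below 0, with a median of -0.47, 0 past the test over all genes and 7 lower adjusted over the list alone (camera adjusted p = 9.61e-14, adjusted p = 0.121 with an estimated correlation). Chemokines and cytokines had a median of 0.21, with Ccl8 past the test and 4 adjusted over the list alone (camera adjusted p = 8.02e-05, adjusted p = 0.175 with an estimated correlation), but the median was 0.13 without young pre-conditioned 2, 0.13 without old pre-conditioned 1 and -0.04 when only brighter probes were kept. MHC class I genes had a median of 0.21, 0 past the test and 1 adjusted over the list alone (camera adjusted p = 0.000448, adjusted p = 0.246 with an estimated correlation). Proliferation genes had a median of 0.13 (camera adjusted p = 0.00159, adjusted p = 0.121 with an estimated correlation), 0 past the test on either adjustment, and lost the call without old pre-conditioned 1 (0.11 to 0.19 over the fits without 1 array, highest without old pre-conditioned 3).

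Other lists moved less evenly with age after injury. Skeletal muscle markers had a median of -0.42 (camera adjusted p = 0.000535, adjusted p = 0.333 with an estimated correlation), but 0.07 without young pre-conditioned 3, the array that held the muscle transcripts, and -0.80 and -0.75 without young pre-conditioned 1 and 2. Adipocyte markers (-0.41, camera adjusted p = 0.00979, adjusted p = 0.246 with an estimated correlation) lost the call without that array or old pre-conditioned 1 (-0.52 to -0.21, with -0.26 without old pre-conditioned 3). Pericyte and smooth muscle markers (-0.15, camera adjusted p = 0.0129, adjusted p = 0.246 with an estimated correlation) lost it without young pre-conditioned 3 or old pre-conditioned 2 (-0.27 to -0.08, lowest without old pre-conditioned 1). Myelin genes (-0.13, camera adjusted p = 0.00159, adjusted p = 0.255 with an estimated correlation) lost it without young pre-conditioned 3 (-0.08) and measured -0.05 without old pre-conditioned 1. Interferon response genes had a median of 0.09 (camera adjusted p = 0.00979, adjusted p = 0.402 with an estimated correlation) and were not called without old pre-conditioned 1 or 2 (0.06 to 0.17, with 0.17 without young and 0.16 without old pre-conditioned 3). T and NK cell markers had a median of 0.15 (camera adjusted p = 0.0213, adjusted p = 0.246 with an estimated correlation), not called without young pre-conditioned 2 or old pre-conditioned 1 or 2 (0.14 to 0.19). In all 6 of these lists 0 members passed over all genes, and adjusted over the list alone 2 pericyte and 2 myelin genes were lower and 0 of the others passed.

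**Figure D5:**
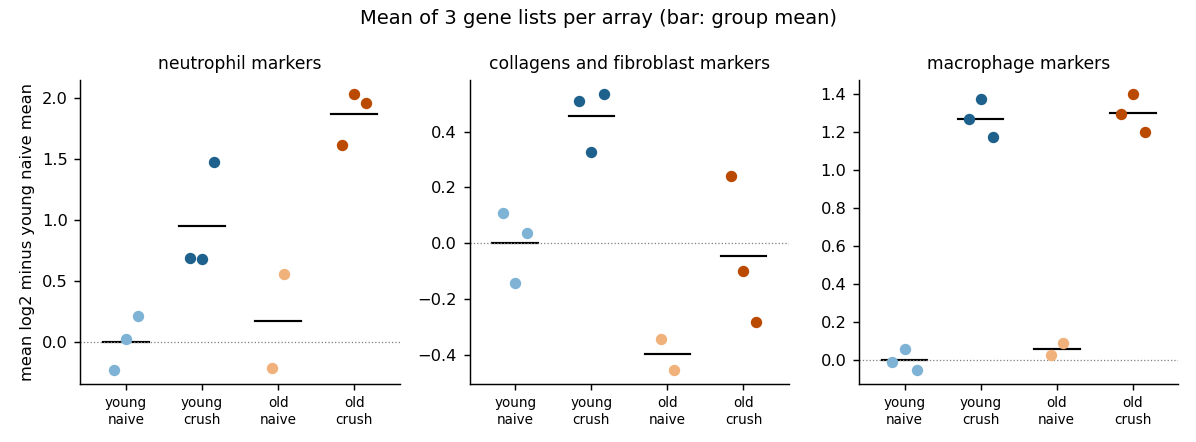
Mean log2 level of neutrophil, collagen and fibroblast, and macrophage markers on each of the 11 arrays, relative to the young naive mean, with each point 1 array and each bar a group mean. Neutrophil scores are 1.61, 2.03 and 1.96 on the old and 0.69, 0.67 and 1.47 on the young pre-conditioned arrays, and macrophage scores of the injured groups overlap.

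Averaged over injury state, which sets 5 old against 6 young arrays, 25 genes were higher and 28 lower in old ganglia by limma. Any other difference between the old and the young animals cannot be told apart from age here. Ccl8 was higher in old ganglia by 1.74 ± 0.11 (adjusted p = 2.06e-05), Csprs by 1.53 ± 0.12 and Azgp1 by 1.10 (0.03 on a second probe). Acer2 was higher by 1.03, Vmn1r181 by 0.79, Mgarp by 0.79, Pcdhb3 by 0.75 and Hsd11b1, whose product regenerates active glucocorticoid, by 0.70 (0.56 and not called on another probe). Lyz2 was higher by 0.54, but its other probes gave 0.01 and -0.11, and its call was lost without old naive 1 or 2 (0.50 to 0.58 over the fits without 1 array). Serpina1e was higher by 0.75 and lost its call without old naive 2 (0.67 to 0.79). Lower were Pmp2 (-1.45 ± 0.17), Lox (-1.35 ± 0.15), Tyrp1 (-1.24 ± 0.11), Vtn (-1.07), Col26a1 (-0.89), Hoxb5 (-0.74), Ednrb (-0.70, -0.91 and not called on another probe) and Dbp (-0.68). Mfap5, a microfibril gene (-0.69), Gjb2, a gap junction gene (-0.67), Acta2, the smooth muscle actin gene (-0.62, but -0.47, -0.31 and -0.46 on other probes, which were not called), Fa2h, which hydroxylates myelin lipids (-0.55), and Col4a1 (-0.52) were lower, and C4b (0.50), Atf3 (0.46) and Pglyrp1 (0.65) higher. Each of these lost its call without old naive 2 and without other arrays too, keeping it in 2 to 7 of the 11 fits. Atf3 passed for age in naive but not in injured ganglia. Npy (0.62 ± 0.13), Gal (0.03 ± 0.10), Jun (0.09 ± 0.10), Sprr1a (0.06 ± 0.15), Gap43 (-0.30 ± 0.22) and Mbp (0.06 ± 0.07) did not pass. The total of 53 genes became 92 without old pre-conditioned 1, 21 without old naive 2, 28 without young naive 3, 29 without old naive 1, 31 without young naive 1 and 32 without young pre-conditioned 1.

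Collagens again led the lists for age averaged over injury state, with Col4a1 past the test over all genes, 9 of 14 lower adjusted over the list alone and a median of -0.42 (camera adjusted p = 1.78e-12, adjusted p = 0.281 with an estimated correlation). Neutrophil markers had 0 past the test, 5 adjusted over the list alone and a median of 0.54 (camera adjusted p = 4.48e-07, adjusted p = 0.281 with an estimated correlation), which was 0.29 without old naive 2. Chemokines and cytokines had 1 and, adjusted over the list alone, 2 higher, with a median of 0.19 (camera adjusted p = 0.000144, adjusted p = 0.281 with an estimated correlation) that was -0.06 when only brighter probes were kept. Of the myelin genes 1 and, adjusted over the list alone, 3 were lower (median -0.13, camera adjusted p = 0.000167, adjusted p = 0.281 with an estimated correlation). Oxidative phosphorylation had 0 past the test, also when adjusted over the list alone (median -0.07, camera adjusted p = 0.00311, adjusted p = 0.298 with an estimated correlation), with the sign turned under median scaling (0.05). It was not called without old naive 1 (-0.09 to -0.05 over the fits without 1 array). On its main probe only, Acta2 was the 1 pericyte and smooth muscle marker that was lower on either adjustment, over all genes and adjusted over the list alone (median -0.13, camera adjusted p = 0.00942, adjusted p = 0.281 with an estimated correlation). This list's call was lost without young pre-conditioned 3 or old pre-conditioned 2 (-0.20 to -0.10, lowest without old pre-conditioned 1). C4b was the 1 complement gene that was higher on either adjustment (median 0.11, camera adjusted p = 0.0151, adjusted p = 0.281 with an estimated correlation), a call lost without young pre-conditioned 2, old naive 2, old pre-conditioned 1 or old pre-conditioned 2 (0.08 to 0.14). Skeletal muscle markers (-0.23, camera adjusted p = 0.0395, adjusted p = 0.586 with an estimated correlation) had a median of 0.03 without young pre-conditioned 3 and lost the call without any of 8 arrays. Fry's p asks whether a list's genes moved on balance one way and not how they compare with other genes. By fry, the adjusted p was 0.0347 for collagens, 0.0347 for chemokines, 0.0347 for central glia and 0.0372 for cholesterol synthesis. Camera called neither central glia (median 0.13) nor cholesterol synthesis (-0.03) here. The other lists that camera called here did not pass fry (adjusted p from 0.0536 for complement to 0.609 for skeletal muscle markers). No list passed fry for age in naive (smallest adjusted p 0.175), age in injured (0.0953) or the interaction (0.705). Over all comparisons, 33 of the 56 list results past camera's threshold did not pass fry, while 11 others passed fry alone.

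The age differences of naive and of injured ganglia come from separate arrays and could be set against each other. A difference other than age between the old and the young animals could appear in both. Acer2, Azgp1, Ccl8, Csprs, Pcdhb3 and Vmn1r181 were higher in old ganglia in both states, 6 genes against 0.0109 if the calls were independent. Col26a1, Hoxb5, Tyrp1 and Vtn were lower in both, 4 genes against 0.00677. Both tests share each gene's variance estimate, which favours the same genes in both, so these counts under independence are likely too low. All 15 genes called in naive ganglia had the same sign in injured ganglia, and the correlation of the age changes across all genes tested, which are not independent replicates, was 0.341.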

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

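The tests of bright arrays, blood and other immune cells in this part were chosen only after the result was seen. Camera, applied to the difference between the old and the young injury response, passed its threshold for 7 gene lists, although no single gene did and none of the calls held with an estimated correlation. Neutrophil markers had a median difference of 0.80 (adjusted p = 5.18e-07, adjusted p = 0.491 with an estimated correlation), above 0 for 10 of 10 members, with Ngp at 1.10 ± 0.47, and the call was lost without old naive 1 (medians 0.44 to 1.12 over the fits without 1 array). Interferon response genes had a median of 0.25 (adjusted p = 1.82e-06, adjusted p = 0.464 with an estimated correlation), above 0 for 20 of 22 members, with Rsad2 at 0.86 ± 0.25, and passed in every fit without 1 array. Their median still ran from 0.14 to 0.39 over those fits, with 0.14 without young naive 1, 0.39 without young naive 2 and 0.39 without old naive 2. MHC class I genes had a median of 0.24 (adjusted p = 0.00265, adjusted p = 0.588 with an estimated correlation), lost without old naive 1 (0.08), and 0.15 without young naive 1 and 0.10 without old pre-conditioned 1. Proliferation genes had a median of 0.17 (adjusted p = 0.00471, adjusted p = 0.295 with an estimated correlation), lost without old naive 2 or old pre-conditioned 1 (0.10 to 0.24), and 0.11 without young naive 2. Regeneration genes had a median of -0.10 (adjusted p = 0.00471, adjusted p = 0.835 with an estimated correlation), lost without young pre-conditioned 1, old naive 2 or old pre-conditioned 1 (-0.18 to -0.06), and -0.18 without old naive 1 and -0.15 without old pre-conditioned 2. Adipocyte markers had a median of -0.47 (adjusted p = 0.00616, adjusted p = 0.464 with an estimated correlation), lost without old naive 2 or old pre-conditioned 1 (-0.63 to -0.30, highest without young naive 2). Skeletal muscle markers had a median of -0.53 (adjusted p = 0.0281, adjusted p = 0.835 with an estimated correlation), which became -0.03 without young pre-conditioned 3, the array with the muscle transcripts, and -0.91 and -0.86 without young pre-conditioned 1 and 2. The call was also lost without young naive 1, old naive 1, old naive 2, old pre-conditioned 1 or old pre-conditioned 3.

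The mean neutrophil score was higher in injured old than in injured young ganglia by 0.923 ± 0.293 (SE). Without the 2 brightest arrays, young pre-conditioned 3 and old pre-conditioned 1, the difference was 1.31 ± 0.0385, so it does not rest on those arrays. They held the highest injured young score (1.47) and the lowest injured old score (1.61), so leaving them out could only raise the difference. The small standard error rests on 2 arrays in each group and is itself uncertain. Red blood cell markers differed by 0.0243 ± 0.335, which lies below 0.5 times the neutrophil difference by little more than its standard error. Their score was 0.87 on old pre-conditioned 2, which had the highest neutrophil score (2.03), but -0.14 on old pre-conditioned 3, where the neutrophil score was 1.96. With this spread the test cannot decide on blood left in the ganglia. Macrophage markers differed by 0.0298 ± 0.0821, which argues against more immune cells of every kind. More neutrophils in injured old ganglia, more transcript per neutrophil, or marrow of the spine taken along with the ganglia may account for the pattern, and none of these was tested.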

How the results depend on the processing

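The fits with array brightness as a covariate and without the 2 brightest arrays were chosen only after seeing the data. Of the genes named, 216 results were past the threshold, and over their alternatives 4762 of 5304 values kept direction and call and 542 kept direction only. This tally leans toward agreement. With all probes tested, the probe with the smallest p stood for each gene, and genes dropped by a filter were not counted. Leaving out an array outside a comparison left its estimate unchanged. For the average over injury state, fitting only the groups compared repeated the main fit. Of the list results 56 were past it, with 1291 of 1512 values kept, 210 without the call and 11 reversed. Among results not past the threshold, 64 gene values and 98 list values became past it. The interaction count was 0 in every alternative. A minimum 2-fold change left 309 and 300 genes for injury in young and old, 6, 10 and 9 for age in naive, in injured and averaged. Only the groups compared gave 911 for injury in old, 2 for age in naive and 12 for age in injured, but 2594 for injury in young against 2084. The stricter filter, which tests fewer genes, gave 3, 8 and 31 for the 3 age counts. Median scaling gave 6 for age in naive, and for age in injured 13 higher and 8 lower in place of 14 and 13. Array weights gave 58 and 105 for age in injured and averaged, array brightness as a covariate 40, 50 and 342 for age in naive, injured and averaged, and leaving out the 2 brightest arrays 86 for the average, 48 of them shared with the 53. The cause was not tested. Leaving out 1 array gave 1415 to 2649 genes for injury in young, 982 to 2283 for injury in old, 2 to 23, 10 to 45 and 21 to 92 for age in naive, injured and averaged, 0 to 0 for the interaction, a correlation of old with young responses of 0.821 to 0.881 and a slope of 0.990 to 1.14. A fit that leaves 1 old naive array takes that array to vary like the other groups.

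When all probes were tested, Mbp after injury in young was -1.05 on the probe with the smallest p, but 0.03 on its brightest probe and 0.11 on another. The chemokine median became -0.0764 (age in naive), -0.0367 (age in injured) and -0.0566 (averaged) under the stricter filter, which drops dim members. The oxidative phosphorylation median became 0.0256 (age in naive) and 0.0454 (averaged) under median scaling, and the cause was not tested. The skeletal muscle median became 0.0675 (age in injured), 0.0434 (averaged) and 0.0731 (interaction) without the 2 brightest arrays. Over the fits without 1 array it ran from -0.799 to 0.0673, from -0.343 to 0.0268 and from -0.912 to -0.0276, each time highest without young pre-conditioned 3, which held the muscle transcripts.

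With the replicate number as a replicate block, the counts were 1929 and 1720 for injury in young and old, 6 for age in naive, 31 for age in injured and 45 for the average. Whether the numbers pair the samples is not known. Deviations from the group means correlated from -0.37 to 0.25 over the 15 same-number pairs (6 above 0.1, median 0.03). Over other pairs they correlated from -0.41 to 0.44 (median -0.05). Deviations within so small a group are tied to each other, so they cannot decide on pairing. A block by chip was not run, as no chip barcodes were in the sources used here. Dim probes had no detection p-values, so how far their signal lay above background is unknown.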

Other observations

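In this part the tests of bright arrays, fibroblasts and single old naive arrays were chosen only after the result was seen. Cdkn1a, which encodes an inhibitor of the cell cycle, rose after crush by 1.72 ± 0.11 in young and 1.66 ± 0.12 in old ganglia, and Igfbp3, a binding protein gene for insulin-like growth factors, by 2.12 ± 0.15 and 2.24 ± 0.16. They are among the 10 measured ageing and senescence genes, of which 3 rose in young and 2 in old ganglia (camera adjusted p = 0.0331 and 0.0583, and 0.138 and 0.19 with an estimated correlation). The list call in young, with a median of 0.22, was lost without young naive 2 (0.15) and without young pre-conditioned 1 (0.18). Of all genes tested, 18.1% were called for injury in young and 16.5% in old ganglia. Between old and young ganglia, where at most 0.460% of all genes were called, 0 of the 10 measured members passed in the naive, injured or averaged comparison, with list medians of 0.02, 0.02 and 0.04 (camera adjusted p = 0.814, 0.956 and 0.753). Some single genes responded within lists that did not pass as a whole. The lysosomal genes Cd63 (1.27 in young, 1.17 in old) and Ctsh (1.22, 1.34), the cholesterol synthesis gene Hsd17b7 (1.11, 1.00), the phosphatase gene Dusp1 (1.10, 0.98) and the neuronal intermediate filament gene Ina (0.62, 0.79) rose at both ages.

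Splits of the arrays were used to ask whether a chance division gives as many genes. For injury in young (2084 genes, highest other split 0) and age in injured (27 genes, highest other 0), 1 of 10 splits each reached the real count, and 10 splits are too few for a share under 0.05. For age averaged over injury state, 1 of 100 splits drawn from 200 (the real one) gave as many as 53 genes. The highest other gave 11 and the median was 0, so a chance division of these arrays is an unlikely source. Chance differences between a few animals are not excluded, since arrays of a group may not be separate animals. The split with 11 placed 0 of the real old arrays in its old groups and is thus close to the real one with the ages exchanged.

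Collagens and fibroblast markers were lower in old ganglia, by a mean of -0.399 ± 0.105 (SE) in naive and -0.505 ± 0.168 in injured ganglia. The naive value argues against the 2 brightest arrays as its source, since both are injured arrays. The 9 collagens differed by -0.617 ± 0.116 averaged over injury state (9 of 9 below 0) and the 5 other members by -0.154 ± 0.0785 (4 of 5 below 0). The collagens thus fell more than the other members. With 5 such members measured, and with the matrix-related genes Lox and Mfap5 outside the list also lower, the split cannot decide whether fibroblasts were fewer. Less collagen transcript per cell, a lower share of one collagen-rich cell type, and age itself may each contribute, and none was tested.

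Atf3 and Npy were higher in naive old ganglia, on both old arrays: Atf3 measured 7.93 and 8.37 against 7.44, 7.35 and 7.19 in young naive ganglia, and Npy 8.18 and 8.80 against 7.45, 7.09 and 7.23. Without 1 old naive array the lower values were 0.612 ± 0.140 for Atf3 and 0.920 ± 0.218 for Npy, over 0.5 times the full differences, which argues against 1 array as the source. Both calls still ended in 8 of the 11 fits without 1 array, among them the fit without old naive 2, which leaves 1 array in the group. The 100 genes that rose most after injury showed a median of 5.96% of their injury response in naive old ganglia (3.73% to 9.03% over the splits), against 16.4% for Atf3 and 21.7% for Npy, which leaves a weak response open, since 0.5 times the Atf3 share lies within the spread of 2.44 (SD). Stress or damage of a few neurons in aged animals may be a cause, and the labels hold nothing to test it with.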
